A study of Mus musculus with 14 samples.

How the data were processed

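The study sequenced RNA of microglia sorted from aged mice after infusion of anti-CD22 or IgG, with 7 libraries per group. Per the submitters' processing notes, reads of 100 bp from both ends were demultiplexed with bcl2fastq, aligned with STAR to mm10, counted per gene with SummarizedExperiment and normalized with DESeq2. Versions, the gene annotation and any read filter are not given in the sources used here. The deposited table holds normalized counts, a signal in which the authors divided each sample's counts per gene by 1 size factor for that sample. Raw reads were not analysed here.

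The table has 24421 entries for 14 libraries, and 0 columns were without a sample. A total of 27 entries with names turned into dates, of which 2 names occur more than once, were left out, at no more than 0.149% of any library's counts. This left 24394 named genes, and 8436 entries were at 0 in every library. Groups and replicate numbers came from the sample titles.

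The main test was limma on log2 of the normalized count plus 1, for 11646 genes with a mean over all libraries of at least 10 normalized counts. It used a mean-variance trend, a two-sided moderated test, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Of 34 fixed lists with 891 entries, 882 entries were found in the table (1 under another symbol), and 28 lists had at least 5 tested members. Mitochondrially encoded genes had 0 entries in the table and were not analysed here. Lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. A list mean is the average per library of log2 values centred per gene. Its group difference has a 95% interval from both group variances and a two-sided exact permutation p over all 3432 assignments of libraries to groups. Adjusted p of lists are adjusted over the 28 lists. Some lists share members.

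Tests, lists, comparisons and the rule for named genes were set before the data were examined. The rule takes Cd22, the 12 genes in each direction past the threshold by fold or else by smallest p (predicted genes passed over), and up to 4 members of each list with the smallest p. After a first look this was narrowed to 4 members for lists past the threshold and 2 for others. Not every gene the rule takes is printed. A few further genes are named as chosen after their values were seen.

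Each library's values were whole multiples of 1 step within a tolerance of 0.1 reads, so whole reads were recovered by dividing by that step. This was used for 13 libraries. The step of anti-CD22 replicate 3, at 1.00925, is close to 1, so whole reads were not claimed for it, although 100% of its values were whole multiples. That library stayed out of the edgeR quasi-likelihood and DESeq2 tests. DESeq2 gave no adjusted p for 3839 genes under its own filter. Reads ranged from 20246743 to 38148494 per library. Counting error was a median of 9.61% of the variance within groups for genes with a mean of 10 to 100 normalized counts, 6.33% from 100 to 1000 and 3.44% above that. No pair of replicates was alike within counting error, with a lowest chi-square per gene of 17.9. The median SE of a log2 fold change was 0.13 and the median 95% margin 0.28. Reads without molecular identifiers are not independent molecules, and no interval here covers counting error alone.

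Transcript length and GC content came from the longest transcript per gene in GENCODE vM21 (GRCm38, the same assembly as mm10), which also gave the coordinates. They were known for 98.7% of tested genes and for 100% of the members of every list. The trend was removed in each library with natural splines. This removal, leaving out the 3 libraries with the steepest trend, the permutation test of lists, DESeq2 without a filter on low values and fry for the marker lists were added after seeing the data. Alternatives set beforehand were other pseudocounts, filters, scalings, variance models, sample weights, a covariate, a replicate block, a threshold of 0.10, count models and leaving out each library.

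The pipeline was tested on simulated counts of 11646 genes in the anti-CD22 against IgG design of 7 against 7. It recovered 61 of 100 genes changed 1.5-fold and 91 of 100 changed 2-fold, all in the right direction, with 11 false calls and 0 lists called. Random splits of the real libraries called a median of 6 lists at the preset correlation. The 0 lists in simulated counts therefore do not carry over to the list tests here. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.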

Results

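RNA sequencing measured the transcriptomes of microglia, the resident macrophages of the brain, from C57BL/6 mice aged 18 months. About 20000 living cells with CD11b and low CD45 on their surface were sorted per sample. The mice had received 1 month of pump infusion into the cerebrospinal fluid of either an antibody that blocks CD22, an inhibitory receptor for sialic acid, or a control IgG. Each group held 7 libraries, made from the side of the brain away from the cannula and named here by group and replicate number. The deposited normalized counts summed to between 27394162 and 29235291 per library. Whole reads were recovered for 13 libraries and ranged from 20246743 to 38148494. The mean was 27122773 ± 4466189 reads (SD, n = 7) for IgG and 30465662 ± 4374222 (SD, n = 6) for anti-CD22. Genes above 0 numbered from 12628 to 13442 per IgG library and from 12700 to 13269 per anti-CD22 library, and the 10 most abundant genes took from 12.3% to 13.9% of the counts. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples.

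The level of the antibody's own target was compared first. Cd22 (chromosome 7: 30865402 to 30880342, GRCm38) was well expressed in both groups, at 1469 ± 279 normalized counts (SD, n = 7) with IgG and 1481 ± 184 (SD, n = 7) with anti-CD22. Its log2 fold change of 0.03 (SE 0.12, 95% interval -0.22 to 0.27, adjusted p = 0.946) was smaller than the spread between libraries, and 4 of 7 anti-CD22 libraries lay above the IgG median. Single libraries ranged from 998 to 1802 normalized counts for IgG and from 1252 to 1716 for anti-CD22.

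Which genes changed after a month of CD22 blockade was tested next over 11646 genes. Ier2, an immediate early gene that is switched on within minutes of a stimulus, fell 1.83-fold, from 598 ± 103 normalized counts (SD, n = 7) with IgG to 326 ± 45.5 (SD, n = 7) with anti-CD22. The range was 466 to 711 in the IgG libraries and 277 to 399 in the anti-CD22 libraries, so the groups did not overlap (chromosome 8: 84661331 to 84662852; log2 fold change -0.87, SE 0.13, adjusted p = 0.0227). It was the 1 gene past an adjusted p of 0.05 by limma, with 1485 genes at an unadjusted p under 0.05 (792 higher, 693 lower) where 582.3 are expected by chance on average. Genes vary together, and the length and GC trend described below differed between the groups, so this excess does not by itself show changed genes. On the reads of 13 libraries DESeq2 called 32 genes (14 higher, 18 lower) and edgeR called 0, with 1027 at an unadjusted p under 0.05.

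Among the 12 genes with the smallest p in the lower direction, all but Ier2 missed the limma threshold. Jun, a subunit of the transcription factor AP-1 (chromosome 4: 95049034 to 95052222), averaged 4227 ± 470 normalized counts (SD, n = 7) with IgG and 2771 ± 580 (SD, n = 7) with anti-CD22, a log2 fold change of -0.63 (SE 0.11, adjusted p = 0.0890). Myc, a transcription factor that drives growth, stood at 2282 ± 529 and 1441 ± 212 (adjusted p = 0.144). Socs3, an inhibitor of JAK-STAT signalling, stood at 1466 ± 218 and 1046 ± 143 (adjusted p = 0.144). The stress-responsive kinase Plk3 had a log2 fold change of -0.54, the pseudokinase Trib1 -0.46, the transcription factor Klf10 -0.56 and the immediate early gene Ier3 -0.69, with adjusted p from 0.108 for Plk3 to 0.163 for Ier3. The remaining log2 fold changes were those of the mitophagy kinase Pink1 (-0.38), the proton pump subunit Tcirg1 (-0.29), the splicing kinase Clk3 (-0.35) and Hps4, which acts in the making of lysosome-related organelles (-0.33, adjusted p = 0.170). With the length and GC trend described below removed, all 12 kept their direction. Most were smaller, among them Pink1 (-0.27), Tcirg1 (-0.20) and Clk3 (-0.24), while Trib1 (-0.47) and Klf10 (-0.56) stayed nearly the same. All 7 of 7 anti-CD22 libraries lay below the IgG median for each of these 12 genes, which their choice by smallest p favours.

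Of the 12 genes with the smallest p in the higher direction, 0 passed the limma threshold. Rlim, an X-linked ubiquitin ligase (chromosome X: 103957163 to 103981284), averaged 926 ± 169 normalized counts (SD, n = 7) with IgG and 1405 ± 168 (SD, n = 7) with anti-CD22, a log2 fold change of 0.61 (SE 0.11, adjusted p = 0.0890). Ggps1, which makes geranylgeranyl diphosphate for protein prenylation (chromosome 13: 14050659 to 14063488), averaged 1359 ± 99.0 and 1801 ± 167, a log2 fold change of 0.40 (SE 0.075, adjusted p = 0.0890). Fastkd5, a factor of mitochondrial RNA processing, stood at 515 ± 83.3 and 790 ± 125 (adjusted p = 0.121). The zinc finger genes Zfp229 (0.88), Zbed4 (0.80) and Zfp84 (0.42), the Polycomb component Rybp (0.60) and the chromatin ubiquitin ligase Msl2 (0.40) were also higher in log2 fold change. So were Phrf1 (0.53), the receptor chaperone Ric3 (0.44), the neuropeptide receptor gene Calcrl (0.51) and the DNA-binding protein gene Nabp1 (0.65, adjusted p = 0.163). With the length and GC trend described below removed, all 12 kept their direction and were smaller, most of all Calcrl (0.31), Msl2 (0.26), Rlim (0.41) and Ggps1 (0.27). All 7 of 7 anti-CD22 libraries lay above the IgG median for each of these 12 genes, which their choice by smallest p favours.

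DESeq2 called 20 of these 24 genes. The count of 1 gene often changed when 1 library was left out, although the log2 fold change of Ier2 stayed from -0.93 to -0.82 in all 14 such fits. It was -0.87 without IgG replicate 2 and -0.88 without IgG replicate 7, where the call was lost. A lost call therefore need not mark a library that carried the difference. Ier2 kept an adjusted p under 0.05 in 6 of these 14 fits, with a range of 0.0139 to 0.101. The value was 0.0542 without IgG replicate 2, 0.0816 without IgG replicate 3, 0.101 without IgG replicate 4, 0.0922 without IgG replicate 5 and 0.0634 without IgG replicate 7. It was 0.0769 without anti-CD22 replicate 1, 0.0835 without anti-CD22 replicate 3 and 0.0797 without anti-CD22 replicate 6, and no gene passed in these 8 fits. Leaving out anti-CD22 replicate 7 gave 43 genes (36 higher, 7 lower), of which 14 were among the 24 just named, and leaving out anti-CD22 replicate 2 or 5 gave 2 genes each.

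**Figure D1:**
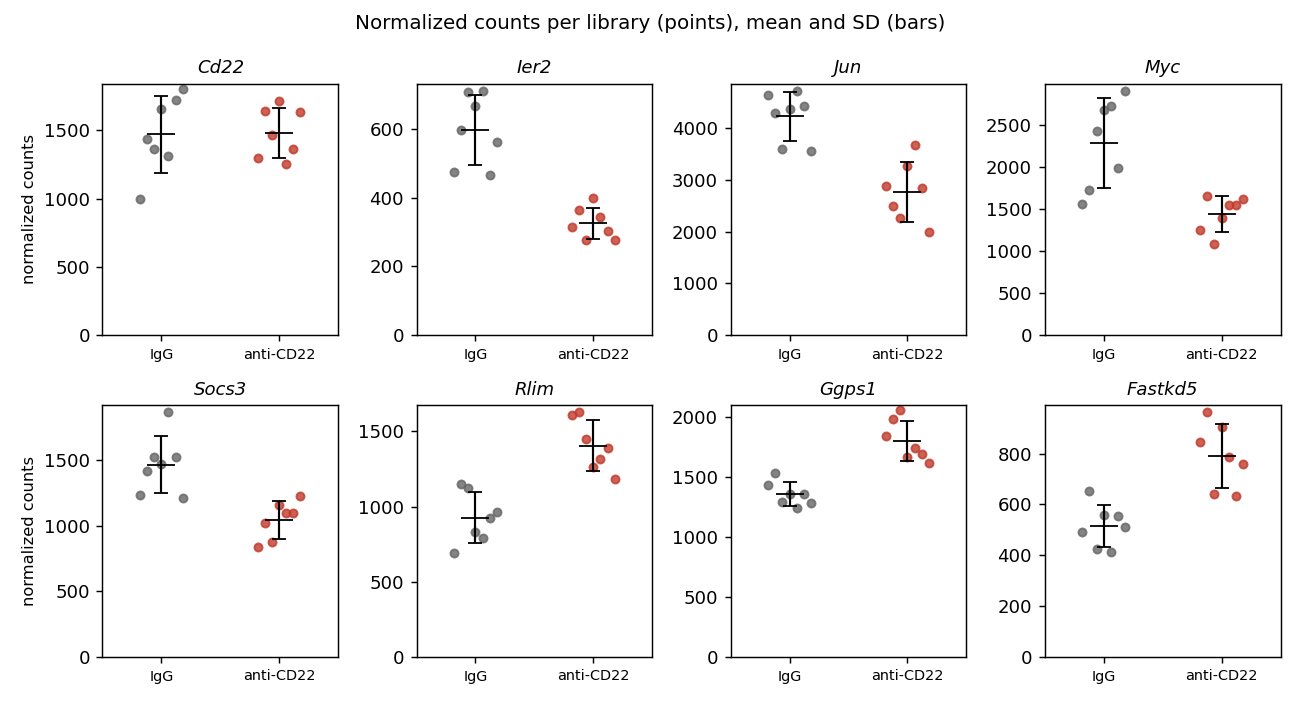
Normalized counts (vertical axes, from 0) of 8 genes in each of the 7 IgG and 7 anti-CD22 libraries (points), with the mean and SD as bars. Cd22 overlaps between the groups, whereas the Ier2 values of 277 to 399 in anti-CD22 libraries all lie under the lowest IgG value of 466.

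Long transcripts were on average relatively more abundant in the anti-CD22 libraries, though not in each of them. Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.381 with transcript length and -0.329 with GC content. The median log2 fold change was -0.09 in the shortest quartile of transcripts and 0.14 in the longest. Within each library, the rho between transcript length and the level relative to the mean of all libraries averaged -0.119 ± 0.105 (SD, n = 7) for IgG and 0.133 ± 0.231 (SD, n = 7) for anti-CD22 (exact permutation p = 0.0280, two-sided). It was steepest in anti-CD22 replicates 1, 2 and 3, at 0.331, 0.305 and 0.342. It was negative in anti-CD22 replicate 6 (-0.0463) and in replicate 7 (-0.284), which lay under the lowest IgG value of -0.273. With the trend removed in each library, the rho with length was 0.0104, and Ier2 had a log2 fold change of -0.71 (SE 0.15, adjusted p = 0.190) against -0.87 (SE 0.13) before. Its call ended because the difference shrank and its error grew slightly, and it did not pass without the 3 steepest libraries either, at a log2 fold change of -0.85.

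Gene groups fixed for the tissue and treatment were compared as lists, and 11 of 28 lists passed an adjusted p of 0.05 by camera with the preset correlation, 9 of them lower and 2 higher with anti-CD22. With an estimated correlation 0 lists passed (5 at an unadjusted p under 0.05). By fry 3 passed, the immediate early, MHC and glycolysis lists, each at adjusted p = 0.0249. By an exact permutation test of the list mean 1 passed, the immediate early list (5 at an unadjusted p under 0.05).

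Immediate early and dissociation stress genes, which respond within minutes to stimulation or handling, fell as a list in anti-CD22 microglia. Of 23 members tested 18 were lower and 5 higher, with a median log2 fold change of -0.29 (camera adjusted p = 1.65e-06). The adjusted p was 0.128 with an estimated correlation. The list mean differed by -0.38 (95% interval -0.60 to -0.16, exact permutation p = 0.00175, adjusted p = 0.0490, n = 7 per group), and 7 of 7 anti-CD22 libraries lay under the IgG median. Ier2, Ier3, Jun and Junb passed when adjusted over the list alone (4 members), and over all genes Ier2 passed. Junb, another AP-1 subunit, stood at 6062 ± 574 normalized counts (SD, n = 7) and 4682 ± 1142 (SD, n = 7). With the length and GC trend removed the list mean differed by -0.30 (95% interval -0.51 to -0.09, exact permutation p = 0.00874, adjusted p = 0.245) and Junb had a log2 fold change of -0.25 (adjusted p = 0.270) against -0.41 before. The permutation call was thus lost, while the camera call was kept (adjusted p = 3.95e-06). The median was -0.20 with the trend removed and -0.14 without the 3 steepest libraries. Without these libraries the list mean differed by -0.33 (95% interval -0.51 to -0.16, exact permutation p = 0.00909, not adjusted over the lists).

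Inflammatory mediators were lower too. The cytokines, chemokines and NF-kB targets fell as a list, with 26 of 30 members lower, a median log2 fold change of -0.16 and 6 of 7 anti-CD22 libraries under the IgG median (camera adjusted p = 0.000217). With an estimated correlation the test gave adjusted p = 0.128, and the list mean differed by -0.14 (exact permutation p = 0.163), or by -0.08 with the length and GC trend removed. Ccl3, Cd14, Cd83 and Nfkbia passed when adjusted over the list alone (4 members), and 0 of them passed over all genes. The chemokine Ccl3 averaged 932 ± 177 normalized counts (SD, n = 7) with IgG and 703 ± 96.0 (SD, n = 7) with anti-CD22. The endotoxin co-receptor Cd14 averaged 35946 ± 2518 and 30139.8 ± 3495, the activation marker Cd83 had a log2 fold change of -0.17, and the NF-kB inhibitor Nfkbia had one of -0.30.

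Disease-associated microglia genes, which microglia raise around amyloid plaques, fell as a list. Of 28 members 26 were lower, with a median log2 fold change of -0.19 and 7 of 7 anti-CD22 libraries under the IgG median (camera adjusted p = 1.24e-05). Camera gave adjusted p = 0.128 with an estimated correlation, and the list mean differed by -0.21 (95% interval -0.50 to 0.07, exact permutation p = 0.127), or by -0.17 with the trend removed. Much of that mean rested on anti-CD22 replicate 5, without which it differed by -0.12. No member passed adjusted over the list alone (0 members). Ank (-0.28), Ccl6 (-0.32), Cox6a2 (-0.57) and the lipid receptor Trem2 (-0.20) had the smallest p, and Ccl6 stood at -0.20 without IgG replicate 5. Trem2 averaged 58891 ± 4712 normalized counts (SD, n = 7) with IgG and 51636 ± 8224 (SD, n = 7) with anti-CD22. Its log2 fold change was -0.04 (adjusted p = 0.861) once the trend was removed, while Ank (-0.27), Ccl6 (-0.28) and Cox6a2 (-0.42) kept most of theirs. The camera call of the list was kept with the trend removed (adjusted p = 0.00183), where the exact permutation p of the mean was 0.177.

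Homeostatic microglia genes did not pass, with 11 members higher and 12 lower (camera adjusted p = 0.865). Their median log2 fold change was -0.00, and it turned positive when libraries were rescaled to the same total or quantile normalized. Tgfbr1, the type I receptor for TGF-beta, had a log2 fold change of 0.37 (SE 0.12, adjusted p = 0.241) and the transcription factor Mef2c one of 0.18. P2ry12 and Tmem119, surface markers of resting microglia chosen after their values were seen, had log2 fold changes of 0.11 (adjusted p = 0.475) and -0.13 (adjusted p = 0.454). All 4 were nearer to 0 with the trend removed, Tgfbr1 at 0.20, Mef2c at -0.00, P2ry12 at 0.03 and Tmem119 at -0.01.

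Genes of TGF-beta signalling rose as a list, with 14 of 21 members higher, a median log2 fold change of 0.12 and 5 of 7 anti-CD22 libraries above the IgG median (camera adjusted p = 0.0366). The list holds inhibitors of the pathway, such as Skil, beside its receptors, so its rise gives no direction of signalling. The adjusted p was 0.349 with an estimated correlation, and the list mean differed by 0.07 (exact permutation p = 0.242), or by 0.05 without anti-CD22 replicate 4 and by 0.02 with the length and GC trend removed, where the median was 0.06. Itgav, Nrros and Tgfbr1 passed when adjusted over the list alone (3 members), and 0 passed over all genes. The integrin Itgav, which helps to release active TGF-beta, averaged 3387 ± 743 normalized counts (SD, n = 7) with IgG and 4713 ± 960 (SD, n = 7) with anti-CD22. Nrros, which holds latent TGF-beta on the microglial surface, moved the other way with a log2 fold change of -0.29, and Tgfbr2 had one of 0.19. Removal of the trend left Itgav at 0.31 against 0.47, Tgfbr1 at 0.20 and Tgfbr2 at 0.06, while Nrros stayed nearly the same at -0.27. The call was lost with the length and GC trend removed (adjusted p = 0.224), without the 3 steepest libraries (0.126), without a filter on low values (0.110) and without a mean-variance trend (0.0747). It was also lost without IgG replicate 3 (0.0578, median 0.14), 4 (0.0902, median 0.12), 5 (0.0611, median 0.09) or 6 (0.0725, median 0.10), and without anti-CD22 replicate 4 (0.117, median 0.11) or 5 (0.146, median 0.10).

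Energy metabolism and translation genes were lower by small amounts. Ribosomal proteins fell as a list, with 78 of 79 members lower and a median log2 fold change of -0.18 (camera adjusted p = 4.62e-13). With an estimated correlation the test gave adjusted p = 0.349, and that correlation between members was 0.62. Nuclear-encoded oxidative phosphorylation genes fell as a list, with 70 of 75 members lower and a median of -0.17 (camera adjusted p = 6.33e-11). Camera gave adjusted p = 0.349 with an estimated correlation. The anti-CD22 libraries lay under the IgG median in 5 of 7 cases for the ribosomal list and in 6 of 7 for the respiratory list. Rps9 (-0.24), Rpl13 (-0.27), Ndufb7 (-0.42) and Cox4i1 (-0.26) had the smallest named p, and 0 members of either list passed adjusted over the list alone. With the length and GC trend removed the list means differed by -0.05 each, against -0.17 and -0.16 before, and Rps9 stood at -0.15, Rpl13 at -0.09, Ndufb7 at -0.20 and Cox4i1 at -0.07. Leaving out IgG replicate 7 brought the ribosomal mean to -0.10. Both camera calls were kept with the trend removed (adjusted p = 0.00241 for the ribosomal list and 0.0179 for the respiratory list).

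Glycolysis genes fell as a list, with 19 of 24 members lower, a median log2 fold change of -0.12 and 6 of 7 anti-CD22 libraries under the IgG median (camera adjusted p = 0.000612). The adjusted p was 0.128 with an estimated correlation, and the list mean differed by -0.09 (95% interval -0.17 to -0.01, exact permutation p = 0.0268, adjusted p = 0.251). The pyruvate kinase Pkm passed when adjusted over the list alone (1 member), at 14340.3 ± 1371 normalized counts (SD, n = 7) with IgG and 12105 ± 941 (SD, n = 7) with anti-CD22. The lactate exporter Slc16a3 had a log2 fold change of -0.25. With the length and GC trend removed the mean differed by -0.06 (exact permutation p = 0.0857), and Pkm had -0.14 against -0.24.

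Antigen presentation genes of the MHC list fell, with 19 of 22 members lower and a median log2 fold change of -0.11 (camera adjusted p = 0.000612). With an estimated correlation the test gave adjusted p = 0.128. The list mean differed by -0.06 (exact permutation p = 0.687), with 3 of 7 anti-CD22 libraries under the IgG median. The class I gene H2-K1 passed when adjusted over the list alone (1 member, log2 fold change -0.25), and the proteasome genes Psme2 (-0.18) and Psmb8 (-0.16) followed. The call was lost with the length and GC trend removed (adjusted p = 0.414, mean difference 0.02), where H2-K1 had -0.13, Psme2 -0.06 and Psmb8 -0.05. The mean turned to 0.01 without IgG replicate 2 or without anti-CD22 replicate 7, and was -0.01 without anti-CD22 replicate 5 and -0.12 without IgG replicate 6.

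Lysosome and v-ATPase genes fell slightly as a list, with 29 of 44 members lower, a median log2 fold change of -0.04 and 6 of 7 anti-CD22 libraries under the IgG median (camera adjusted p = 0.0216). Camera gave adjusted p = 0.427 with an estimated correlation, and the list mean differed by -0.04 (exact permutation p = 0.0851), or by -0.01 with the trend removed. Tfeb, the transcription factor that drives lysosomal genes, passed when adjusted over the list alone (1 member), at 1525 ± 155 normalized counts (SD, n = 7) with IgG and 1205 ± 122.8 (SD, n = 7) with anti-CD22. The pump subunit Atp6v1f had a log2 fold change of -0.23. Both were smaller with the trend removed, Tfeb at -0.19 against -0.34 and Atp6v1f at -0.08. The call was lost with the trend removed (adjusted p = 0.851, median 0.01), without the 3 steepest libraries (0.136), with rescaling to the same total (0.0674), with quantile normalization (0.444) and by edgeR (0.0703). It was also lost without IgG replicate 5 (0.0690) or 7 (0.0936), and without anti-CD22 replicate 4 (0.0625) or 5 (0.0864), with medians from -0.04 to -0.02.

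Cell cycle genes fell as a list, with 27 of 34 members lower, a median log2 fold change of -0.28 and 5 of 7 anti-CD22 libraries under the IgG median (camera adjusted p = 0.00330). The adjusted p was 0.349 with an estimated correlation, and the list mean differed by -0.42 (95% interval -0.97 to 0.12, exact permutation p = 0.114). The replication helicase subunit Mcm6 averaged 933 ± 81.0 normalized counts (SD, n = 7) with IgG and 769 ± 77.8 (SD, n = 7) with anti-CD22. Rrm2, a ribonucleotide reductase subunit, averaged 123.2 ± 62.6 and 71.1 ± 102 (SD, n = 7 per group), the latter with anti-CD22 replicate 1 at 288 and a mean of 34.8 without it. No member passed adjusted over the list alone (0 members), and the call was lost without IgG replicate 6 (adjusted p = 0.0558, median -0.20). The camera call was kept with the length and GC trend removed (adjusted p = 0.00154) and without the 3 steepest libraries (adjusted p = 0.00348). With the trend removed the mean differed by -0.43 (exact permutation p = 0.110), and Mcm6 had a log2 fold change of -0.34 against -0.28 before.

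Genes close to CD22 biology and phagocytosis did not pass as lists. Siglecs and ITIM signalling genes had 17 members higher and 8 lower (camera adjusted p = 0.205), among them the sialic acid receptor Cd33 (log2 fold change 0.17) and the kinase Syk (0.31). Phagocytic receptors had 17 higher and 10 lower (adjusted p = 0.537), and the nucleotide receptor P2ry6 had a log2 fold change of -0.20. Sialic acid metabolism had 8 higher and 15 lower (adjusted p = 0.178), and Cmas, which activates sialic acid for transfer, passed when adjusted over the list alone (1 member, -0.28) while the sialidase Neu1 had a value of -0.16. Fc receptors had 2 higher and 7 lower (adjusted p = 0.175, exact permutation p of the mean = 0.0449, permutation adjusted p = 0.251), with Fcer1g at -0.18 and Fcgrt at -0.12. Their mean differed by -0.06, or by -0.00 with the length and GC trend removed (exact permutation p = 0.971). Complement genes had 9 higher and 6 lower (adjusted p = 0.865), with a positive median of 0.09 and mean of 0.04 beside a camera direction that was down. That mean turned to -0.07 without IgG replicate 3 or anti-CD22 replicate 2 and to -0.05 without IgG replicate 5 or anti-CD22 replicate 1, and it was 0.16 without anti-CD22 replicate 7, so its sign rested on single libraries. The integrin subunit Itgam had a log2 fold change of 0.19 and C1qb one of -0.20. Removal of the trend left Cd33 at 0.01 (adjusted p = 0.981), P2ry6 at -0.10, Neu1 at -0.06, Fcer1g at -0.04, Fcgrt at -0.01, Itgam at 0.12 and C1qb at -0.04, while Syk at 0.27 and Cmas at -0.22 kept most of their difference.

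The other lists did not pass either. Type I interferon genes had 21 members higher and 15 lower (adjusted p = 0.639), and their median of 0.03 was positive while the mean of -0.06 and the camera direction were negative. The mean was 0.00 without anti-CD22 replicate 6, -0.02 without anti-CD22 replicate 7 and -0.11 without anti-CD22 replicate 1 or 5. Ifit2 had a log2 fold change of 0.41 and Ifi27l2a one of -0.50. Cholesterol biosynthesis had 7 higher and 18 lower (adjusted p = 0.272, exact permutation p of the mean = 0.0431, permutation adjusted p = 0.251). Its 1 member past the threshold adjusted over the list alone was Ggps1, which rose against the lean of the list (log2 fold change 0.40), while Dhcr7 stood at -0.18. Cholesterol efflux and lipid droplets had 10 higher and 11 lower (adjusted p = 0.379), with Lpl at -0.44, or -0.29 without IgG replicate 6, and Nr1h2 at -0.19. Senescence and p53 targets had 6 higher and 15 lower (adjusted p = 0.183, exact permutation p of the mean = 0.0303, permutation adjusted p = 0.251), with Bax at -0.24. With the trend removed the exact permutation p of the mean was 0.0350 for cholesterol biosynthesis and 0.0775 for senescence. The unfolded protein response and heat shock list had 12 higher and 19 lower (adjusted p = 0.301), with Herpud1 at -0.20 and Xbp1 at -0.16. Iron handling had 7 higher and 10 lower (adjusted p = 0.221), and its median of -0.06 and camera direction were negative while its mean of 0.06 was positive. That mean was 0.00 without IgG replicate 3, 0.02 without IgG replicate 6 and 0.12 without anti-CD22 replicate 5. In it Ireb2 (0.68), Slc11a2 (-0.24), Ftl1 (-0.25) and Pcbp1 (-0.19) passed when adjusted over the list alone (4 members), the last pair chosen after their values were seen. Several of the genes just named were nearer to 0 with the trend removed, with Ifi27l2a at -0.30, Nr1h2 at -0.06, Bax at -0.04, Herpud1 at -0.12, Xbp1 at -0.09, Ftl1 at -0.08 and Pcbp1 at -0.07. Also nearer to 0, but with most of their difference kept, were Ifit2 at 0.32, Ireb2 at 0.47, Ggps1 at 0.27 and Dhcr7 at -0.14. Lpl at -0.52 and Slc11a2 at -0.28 were further from 0. In the interferon, homeostatic, complement, Fc receptor, phagocytic, Siglec, cholesterol efflux, senescence and unfolded protein lists 0 members passed adjusted over the list alone.

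**Figure D2:**
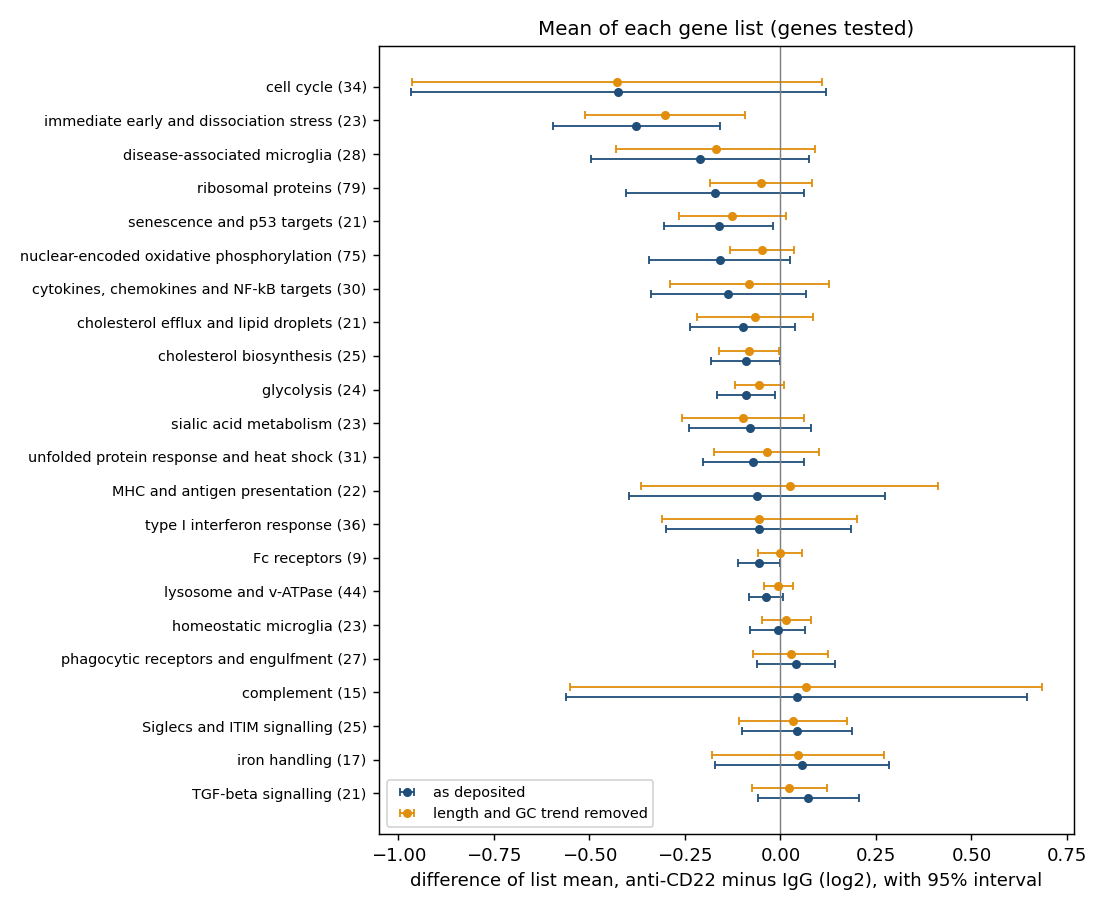
Difference of each list mean between groups (horizontal axis, log2, anti-CD22 minus IgG) with its 95% interval, for 22 lists, as deposited and with the length and GC trend removed. The immediate early list lies at -0.38 and at -0.30 once the trend is removed, and both intervals exclude 0.

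Which other cell types the sorted population held was asked with marker lists, of which 6 had enough members to test. Border-associated macrophage markers rose as a list, with 14 of 15 members higher, a median log2 fold change of 0.55 and 5 of 7 anti-CD22 libraries above the IgG median (camera adjusted p = 0.0154). With an estimated correlation the test gave adjusted p = 0.461, and the list mean differed by 0.77 (95% interval -0.70 to 2.24, exact permutation p = 0.268), or by 0.48 without IgG replicate 6. The scavenger receptor Stab1 averaged 5119 ± 1014 normalized counts (SD, n = 7) with IgG and 5962 ± 823 (SD, n = 7) with anti-CD22, and the lectin Cd209a averaged 16.1 ± 34.4 and 60.1 ± 63.6 (SD, n = 7 per group). Without IgG replicate 2, at 92.3, the IgG mean of Cd209a was 3.45. The call was lost without the 3 libraries steepest in length trend (adjusted p = 0.823, median -0.01), by edgeR (0.0600) and by DESeq2 (0.230, or 0.172 without the filter on low values). It was also lost without IgG replicate 3 (0.0659, median 0.46), 4 (0.0591, median 0.27) or 6 (0.186, median 0.21), and without anti-CD22 replicate 2 (0.0647, median 0.29).

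The remaining marker lists did not pass. Monocyte and dendritic cell markers had 5 members higher and 9 lower (camera adjusted p = 0.865), with Zbtb46 at a log2 fold change of 0.54, or 0.35 without IgG replicate 5. Neutrophil markers had 3 higher and 10 lower (adjusted p = 0.639), with Cxcr2 at 21.2 ± 52.0 normalized counts under IgG and 0.396 ± 0.729 under anti-CD22 (SD, n = 7 per group) and Il1r2 at 21.8 ± 24.1 and 13.2 ± 15.9. IgG replicate 1 held most of the Cxcr2, at 138.8, and without it the IgG mean was 1.56, while the anti-CD22 mean was 0.153 without replicate 5. For Il1r2 the IgG mean was 13.5 without IgG replicate 1, at 71.7, and the anti-CD22 mean was 7.87 without replicate 7, at 45.5. Astrocyte markers had 4 higher and 4 lower (adjusted p = 0.865), with F3 at -0.40 and with Aldh1l1 at 52.5 ± 46.8 normalized counts under IgG and 87.5 ± 51.1 under anti-CD22 (SD, n = 7 per group). Oligodendrocyte markers had 0 higher and 6 lower (adjusted p = 0.234), with Cnp at -0.17 and Mag at -0.10, the latter from -0.16 without IgG replicate 5 to -0.04 without IgG replicate 4. Endothelial and mural markers had 5 higher and 3 lower (adjusted p = 0.801), with a median of 0.05 beside a mean of -0.14 and a camera direction that was down, and with Slc2a1 at -0.11 and Flt1 at -1.21, or -0.61 without anti-CD22 replicate 5, where it was at 0. The list mean was -0.01 without anti-CD22 replicate 5, -0.05 without anti-CD22 replicate 6 and -0.27 without anti-CD22 replicate 4. Cnp stood at -0.11, Mag at 0.00 and Slc2a1 at -0.07 with the trend removed. Of the marker lists too small to test, 3 B cell, 1 T and NK cell, 3 neuron, 1 red blood cell and 4 choroid plexus markers passed the filter on low values. In each of the 6 marker lists tested 0 members passed adjusted over the list alone.

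**Figure D3:**
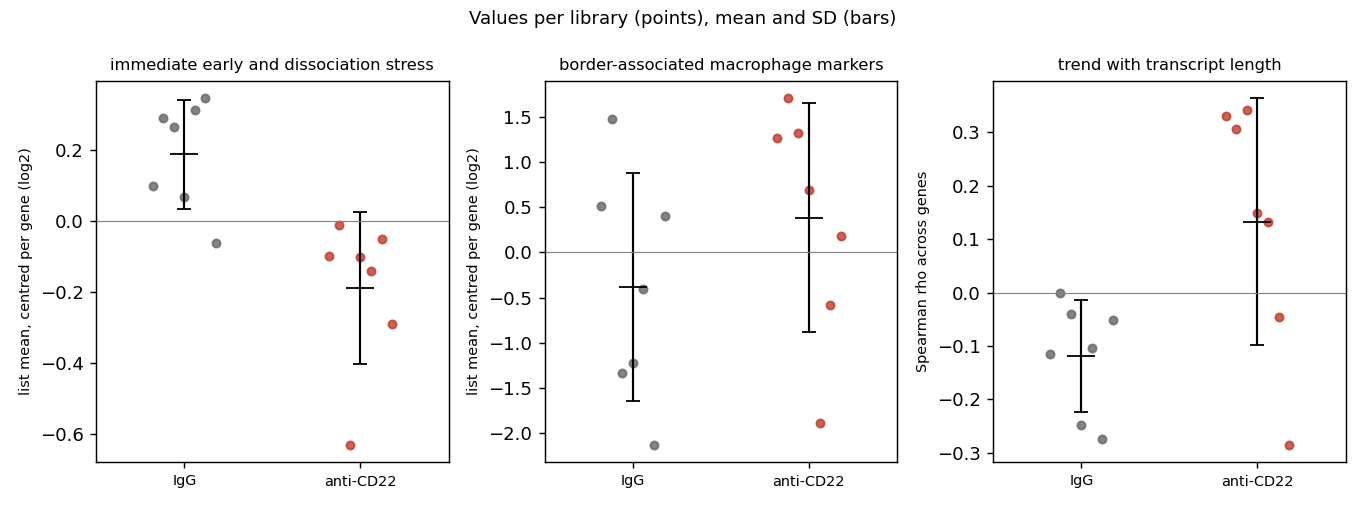
List means per library (log2, centred per gene) for immediate early genes and border-associated macrophage markers, and the Spearman rho with transcript length, for 7 libraries per group (points) with the mean and SD as bars. The rho averages -0.119 for IgG and 0.133 for anti-CD22.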

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

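Apart from the splits of the samples, the tests in this part were chosen only after the gene and list results were seen. The bounds of the tests were set before they were run for the trend and the 3 steep libraries, and afterwards for the trend as the whole cause, dissociation stress and macrophage share.

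The immediate early list was lower in anti-CD22 microglia by -0.38 in its mean. With the length and GC trend removed the difference was -0.301507 (95% interval -0.511 to -0.0918), so most of the difference in these libraries remained. The interval describes the remaining difference and not the share removed. It reaches past the bound of -0.1 set beforehand, so whether the remaining difference lies beyond that bound stays open. By a criterion written afterwards, an interval under 0, the trend is argued against as the whole cause (exact permutation p = 0.00874), although the p adjusted over 28 lists was 0.245. Stress during tissue dissociation cannot be told apart from an effect of the antibody, since 9 heat shock genes differed by -0.00836573 with a 95% interval of -0.361 to 0.345. Lower stimulation of microglia by the antibody may also be at work, and that was not tested.

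The ribosomal and oxidative phosphorylation lists were lower by -0.165 in their joint mean. With the length and GC trend removed the difference was -0.0498204 (95% interval -0.155 to 0.0554), barely inside the bound of 0.05 set beforehand. A trend between libraries in transcript length may thus account for most of it, whatever gave rise to that trend. The trend differed between the groups and was fitted over all genes, these lists included. Its removal would also take out an effect of the antibody that follows transcript length or GC, so the test cannot tell these apart. The interval of the difference reaches past the bound of 0.05, and both camera calls were kept with the trend removed. Without anti-CD22 replicates 1, 2 and 3 the difference was -0.0647676 (95% interval -0.293 to 0.164), which leaves open whether these libraries alone carry the pattern. A lower demand for translation and respiration after blockade stays open as untested.

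Border-associated macrophage markers were higher by 0.77 in their list mean, with an exact permutation p of 0.268. A share of macrophages that differs between libraries of both groups is a candidate explanation, since the members rose and fell together within groups with a mean pairwise correlation of 0.508349. The levels were modest, with Mrc1 at 289 ± 187 and 423 ± 280 normalized counts and F13a1 at 167 ± 165 and 359 ± 291 (SD, n = 7 per group), both named after their values were seen. Stab1 at 5119 normalized counts is far above the others, so microglia may express it, and 4 of the 15 markers also stand in another list. The sort for low CD45 would remove macrophages with high CD45, and an effect of the antibody on macrophages stays open as untested.

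The number of genes called does not exclude chance. Of 100 splits of the samples drawn from 1716, 5 gave at least as many genes as the real split, the real one included. The real split gave 1, and the highest other gave 12, several times the real count. That split parted the libraries along the first principal component (exact permutation p = 0.0105) and not along the length trend (exact permutation p = 0.511), so it points to a structure of the samples across both groups, looked at only after the count was seen. For the number of gene lists under the preset correlation, 2 of 100 splits gave as many, the real one included, which is under the bound set beforehand. So many lists were thus uncommon among the splits, but chance is not excluded, since another split reached the same number. Nor does the count tell the antibody from the length trend, which also differed between the groups. The real split gave 11, the highest other gave 11 and the median of the others was 6. With an estimated correlation 0 lists passed, and the splits do not speak for any single list.

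Single libraries stood apart from the other 6 of their group in 11 of 250 groups examined, where chance alone gives about 1 in 20, so these are in the range of chance. Each value is the gap to the nearest library as a share of the group's range, on the log2 scale. Calcrl was low in IgG replicate 5, at 665 normalized counts against 893 to 1092 (gap 0.59566). Tcirg1 was low in anti-CD22 replicate 3, at 4350 against 5066 to 5555 (gap 0.62297). Clk3 was low in anti-CD22 replicate 7, at 1388 against 1641 to 1861 (gap 0.571143). Ifit2 was high in IgG replicate 3, at 1092 against 533 to 711 (gap 0.598054). Tgfbr2 was low in anti-CD22 replicate 7, at 25686 against 34038 to 38124 (gap 0.712873). Ireb2 was low in IgG replicate 3, at 182 against 359 to 495 (gap 0.678791). Slc11a2 was low in anti-CD22 replicate 4, at 1819 against 2025 to 2166 (gap 0.612846). Il6st, chosen after its values were seen, was low in anti-CD22 replicate 7, at 10731 against 15129 to 17651 (gap 0.690257). The mean of the disease-associated list was low in anti-CD22 replicate 5, at -0.67 against -0.16 to 0.12 (gap 0.642536), and without it the group difference of -0.21 was -0.12. The mean of the lysosome list was high in anti-CD22 replicate 7, at 0.07 against -0.05 to -0.01 (gap 0.657589). The mean of the cholesterol biosynthesis list was high in anti-CD22 replicate 1, at 0.05 against -0.09 to -0.03 (gap 0.572078).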

How the results depend on the processing

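The removal of the length and GC trend, leaving out the 3 steepest libraries, the exact permutation test of lists, DESeq2 without a filter and fry for marker lists were chosen after seeing the data. Cd22 stayed uncalled under every alternative run, with log2 fold changes from -0.06 to 0.08. Of 3033 values of named genes under the alternatives, 2950 stayed on their side of the threshold, 12 lost and 71 gained a call. Of 977 list values 918 stayed, 58 lost and 1 gained a call. None reversed among called values, judged for lists by the direction of camera, although the median of the macrophage markers turned to -0.01 without the 3 steepest libraries and that of the lysosome list to 0.01 with the trend removed. Another 45 of 4042 values changed sign without a call on either side. No scaling moved the median of all genes by more than 0.0123.

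The count of genes, 1 by limma, was 0 with no mean-variance trend, 8 with sample weights, 2 with the first principal component as covariate, 4 at a threshold of 0.10, and 0 to 43 when leaving out 1 library. On recovered reads of 13 libraries it was 0 by edgeR (1027 at an unadjusted p under 0.05), 32 by DESeq2 and 40 by DESeq2 without the filter, of which 31 were shared. It was 0 with the trend removed and 0 without the 3 steepest libraries, where fewer samples were compared. Limma without anti-CD22 replicate 3, the library absent from the reads, also gave 0. The count of lists, 11, was 0 with an estimated correlation, 3 by fry and 1 by exact permutation, and 8 to 12 otherwise. The count of marker lists, 1, was 0 by edgeR, 0 by DESeq2 with or without the filter, 0 without the 3 steepest libraries, 0 with an estimated correlation, 0 by fry, 0 by exact permutation, and 0 to 1 when leaving out 1 library. Apart from the smaller number of samples, the cause was not tested.

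With the replicate block the count of genes was 2. Nothing in the labels says that equal numbers share a day or litter, and correlations between samples of equal number, from -0.145 to 0.160, exceeded 0.1 in 2 of 7 pairs. Depth limited low genes most, though counting error was only a median of 9.61% of the variance within groups for those with a mean of 10 to 100 normalized counts.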

Other observations

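The tests of zinc finger genes and of ERK-induced genes were chosen only after the result was seen.

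Zinc finger genes of the Zfp series, a large family of transcriptional regulators, leaned upward in anti-CD22 microglia. Of 319 tested members 246 had a positive log2 fold change, and their mean was higher by 0.17 (95% interval 0.08 to 0.27, exact permutation p = 0.00350). Many have long transcripts, so the length and GC trend was removed, which left a difference of 0.120763 (95% interval 0.0505 to 0.191, exact permutation p = 0.00350). A rise of this family beyond the length trend is a hypothesis that these values are consistent with, found and tested on the same libraries.

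Spry1, an inhibitor of growth factor signalling, averaged 897 ± 154 normalized counts (SD, n = 7) with IgG and 630 ± 92.5 (SD, n = 7) with anti-CD22, a log2 fold change of -0.50 (adjusted p = 0.170). Dusp6, a phosphatase of ERK, had one of -0.40 (adjusted p = 0.170). Neither passed, and both were chosen after their values were seen. Lower output of the ERK pathway might link them, yet 6 other ERK-induced genes differed by 0.0615133 (95% interval -0.158 to 0.281, exact permutation p = 0.544), and with Dusp6, Spry1 and Myc included the 9 genes differed by -0.131. The interval is too wide to tell.

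Without anti-CD22 replicate 7, the 43 genes past the limma threshold included receptor genes, chosen after their values were seen. Il6st, the shared receptor subunit of the interleukin 6 family, had a log2 fold change of 0.48 (adjusted p = 0.0239). Tgfbr1 had 0.47 (adjusted p = 0.0264), Tgfbr2 had 0.26 (adjusted p = 0.0252) and Itgav had 0.59 (adjusted p = 0.0455). With all libraries Il6st stood at 0.39 (adjusted p = 0.170). The library left out had a length rho of -0.284, opposite to that of most of its group. With all libraries and the length trend removed, Il6st had 0.24 (adjusted p = 0.217), Tgfbr1 0.20 (0.445), Tgfbr2 0.06 (0.646) and Itgav 0.31 (0.408), so 0 of these 4 passed. Of the 43 genes 14 were also called by DESeq2.

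S100a9, an abundant neutrophil transcript chosen after its values were seen, differed widely between libraries of both groups. It reached 6456 normalized counts in IgG replicate 1, 2246 in IgG replicate 7 and 1293 in anti-CD22 replicate 4, and without IgG replicate 1 the IgG mean of 1397 was 554. It was at 0 in IgG replicate 3 and in anti-CD22 replicates 1, 5 and 6.

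The first principal component held 19.2% of the variance and did not separate the groups (exact permutation p = 0.946). The second held 10.8% (exact permutation p = 0.0326).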
